A study of Mus musculus with 5 samples.

How the data were processed

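The series holds single-cell ATAC-seq of 5 libraries of tdTomato-positive cells from C57BL/6J mice, 1 of fascia and 4 of epithelioid sarcomas. Per the labels' protocols, the cells were sorted by flow cytometry from mice treated with tamoxifen (2.5 mg in 100 uL for 5 days, followed by 10 days of washout). The deposited files are matrices of counts per called peak and barcode, with 1 peak set per library. Reads were processed with bcl2fastq and Cell Ranger ATAC 1.1.0 against mm10, per the submitters' processing notes, whereas the file headers name version 2.0.0 for 4 libraries and 1.0.1 for sarcoma 3. The cause of this difference is not given in the sources used here, and sarcoma 3 was regarded as its own technical batch. No fit had a term for this batch. Sarcoma 3 entered each main fit as a replicate and was left out only in alternatives. The deposited counts were mostly even (83.8% to 91.7% of values), as cut sites counted in pairs would be, and they were used as counts of cut sites. No raw reads, fragment files or reference genome were analysed here.

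Counts were summed over all deposited barcodes of a library, since cells of a sample are not replicates. Total counts in peaks were 361.565, 176.524, 75.9459, 201.604 and 207.031 in units of 1e6 for fascia and sarcomas 1 to 4, over 197002, 97759, 95271, 93670 and 88429 peaks of median width 887, 875, 879, 644 and 875 bp. The widest peaks were 2378, 2066, 1887, 72535 and 1935 bp, and sarcoma 3 had 8251 peaks over 2500 bp. Peaks off the named chromosomes (55, 53, 54, 0 and 65) stayed in the totals and out of gene and region tests. A count of 3 is worth 0.0115, 0.0161, 0.0388, 0.0135 and 0.0124 CPM in these libraries, a floor that covers counting error only. Between 102 and 217 barcode sequences were shared by any pair of libraries.

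The gene table carries no strand, so a promoter was taken as the gene end, within 1000 bp, that held the most counts in any of the 4 libraries without wide peaks, for 21887 protein-coding genes. The fixed plan named the transcription start instead. A first rule, the mean over all 5 libraries, was replaced after it had picked the other end of Smarcb1 because of a wide peak in sarcoma 3. Counts of all peaks that overlap the window by at least 1 bp were added. Because each library has its own peaks, an uncalled peak is not a count of 0, and tests used only genes with a peak in every library compared. Printed levels are CPM divided by a library factor made from TMM factors and the counts at tested gene ends (0.724, 1.06, 1.02, 1.10 and 1.16), a scaling added after unscaled CPM had put most genes above fascia in the sarcomas. Merged regions (233270) were made from peaks of all libraries that overlap by at least 1 bp, and 42625 held a peak in all 5.

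Promoters and regions were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The fit of 4 sarcomas against 1 fascia library leaves 3 residual degrees of freedom, all from the sarcomas, and assumes that fascia would vary like them. Head (2) against body (2) sarcomas leaves 2 residual degrees of freedom, and the smallest exact permutation p of such a split is 0.333. On simulated data with 50 genes changed at each size, the fit of sarcomas against fascia recovered 0, 6, 25 and 42 of them at 2-, 4-, 8- and 16-fold with 6 false calls, the same fit with peaks up to 2500 bp 13, 24, 41 and 49 with 11 false calls, the region fit 0, 0, 5 and 23 with 2 false calls, and the head against body fit 1, 21, 41 and 50 with 6 false calls. The 25 gene lists, written before the data were examined, were tested with camera in limma 3.58.1 (preset correlation 0.01), and with an estimated correlation and fry as alternatives. DESeq2 1.42.0 served as the other tool. When each library in turn was set against the rest, edgeR called 0 genes for fascia and for sarcomas 1, 2 and 4 and 403 for sarcoma 3, and with peaks up to 2500 bp 1 for fascia, 15 for sarcoma 4 and 0 for the others.

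Each library was clustered on its own 50000 most covered peaks in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0 (TF-IDF, 30 latent components without the first, 20 neighbours) and leidenalg 0.10.2 with igraph 0.11.9 at resolution 0.5. No doublet caller was run and no doublets were removed. Barcodes over 3 times their library's median, which can hold doublets, numbered 67, 286, 1157, 1132 and 1286 and were left out only as an alternative. A cluster was named after the leading of 12 fixed types only where the mean log2 fold of its markers over the other barcodes was at least 1 and at least 3 of them were raised. A cluster stayed unnamed where markers of another type outnumbered its own among its 10 highest genes, or where its depth was more than 3 times below the library's median with none of its own markers among them. Figures were drawn with matplotlib 3.10.9. Intervals for counts are exact Poisson and for shares exact binomial, at 95%. Chromosome shares were taken over regions with a peak in all 5 libraries, with their spread over bins of 10 Mb.

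The tests, the samples, the lists and most alternatives were fixed before the data were examined. The rule for named genes asked for the 10 highest and 10 lowest of the genes that passed edgeR with every sarcoma on the same side, 8 genes each way among promoter peaks in sarcomas or fascia alone, the targeted genes, up to 2 members of each list with the largest change where none passed, and 4 genes per sarcoma. No gene passed edgeR, so after the results were seen the 8 highest and 8 lowest of DESeq2's calls, list members with an unadjusted p under 0.05, and the genes with a sarcoma peak and no fascia peak within 3000 bp were also named. Of the genes that these rules name, 2 are not reported here. Alternatives fixed at the start were other scaling, a filter of 5 CPM, an offset for peak width, barcodes over 3 times the median or named clusters left out, gene bodies with a flank of 2000 bp, a 500 bp window, uncalled peaks as 0, the 88429 densest peaks, peaks of at least 2 CPM, reciprocal overlap of 50%, Leiden resolution 1 and each sarcoma left out. Alternatives added later were peaks up to 2500 bp, clusters with 3 raised markers left out, both gene ends, no peak within 3000 bp, and levels per base pair. Motif shares were left out because they need a genome.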

Results

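Chromatin accessibility was measured by single-cell ATAC-seq, in which a transposase cuts open chromatin and the cut sites are counted per cell, in 5 mouse libraries sorted for the lineage reporter tdTomato. The fascia library (1 sample) held quiescent mesenchymal progenitors of mice that carry Cre in Hic1, a transcriptional repressor, and a tdTomato reporter in Rosa26 (Hic1CreERT2/CreERT2;Rosa26LSLtdTomato/+). The other 4 libraries held epithelioid sarcomas of mice that also carry floxed alleles of Smarcb1, a core subunit of the SWI/SNF chromatin remodelling complex (Hic1CreERT2/CreERT2;Rosa26LSLtdTomato/LSLtdTomato;Smarcb1FL/FL). They were taken from the shoulder (sarcoma 1), the head (sarcoma 2), the head/ear (sarcoma 3) and the hip (sarcoma 4). The sarcomas thus also carry 2 reporter alleles where fascia carries 1, so the reporter dose differs with the group. All mice received 2.5 mg tamoxifen a day for 5 days at 8 weeks of age. The labels give 10 days of washout for all, but name the tumours as sarcoma cells at endpoint 1 to 4. The time from tamoxifen to collection may thus differ between fascia and sarcomas, and cannot then be told apart from the group. The files held 361564960 counts in 9977 barcodes for fascia, 176524140 in 7897 for sarcoma 1, 75945907 in 10580 for sarcoma 2, 201604039 in 11714 for sarcoma 3 and 207031086 in 14486 for sarcoma 4. The median barcode held 35303 counts in fascia and 19221, 4893.5, 12843.5 and 10643.5 counts in sarcomas 1 to 4. The labels do not say whether the sarcomas came from separate animals, so p-values measure the spread between these samples. Sarcoma 3 was processed with another software version and was the only library with peaks over 2500 bp, which reached 72535 bp and held 47.3% of its counts. Levels are given as scaled CPM, the counts in a peak relative to all counts in the library's peaks, after division by a library factor, and intervals are 95% exact intervals that cover counting error only.

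Smarcb1, the gene that the floxed alleles target, had no called peak at its high end in 3 of the 4 sarcomas. In fascia the peak at the high end of the gene (mm10, chromosome 10, 75921010 to 75921943) held 37.5 CPM (interval 36.7 to 38.2). No peak was called there in sarcomas 1, 2 and 4, and a peak in sarcoma 3 (75920916 to 75922079) held 5.60 CPM (5.29 to 5.92), a level 6.69-fold below fascia. A further fascia peak inside the gene (75898631 to 75899533) held 36.9 CPM, against 2.33 CPM in sarcoma 1 and 3.69 CPM in sarcoma 2, and none was called in sarcoma 4. The peak near the low end was called in all 5 libraries, at 5.03 CPM in fascia and 6.60, 7.42, 20.3 and 3.79 CPM in sarcomas 1 to 4, where the sarcoma 3 peak was 2376 bp wide and ran over the position of the inner fascia peak. Counts outside called peaks were not used here, so an uncalled peak gives no level.

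Within sarcoma 3 the Smarcb1 peak was unevenly spread over the clusters of cells. Clusters 2, 7, 8, 9 and 10, with 3637 barcodes (31.0% of the library), held 16.3, 18.2, 22.9, 16.3 and 24.4 CPM at the high end, and clusters 1, 3, 4 and 5, with 64.2% of the barcodes, held 0.863, 0.536, 0.349 and 0.137 CPM. Cluster 6 held 3.84 CPM, and its barcodes had a median of 63001 counts. The 14 clusters of fascia lay between 27.4 and 69.8 CPM. The loci of the other engineered alleles kept their peaks in every library. At Hic1 the main high-end peak held 53.5 CPM in fascia and 71.5, 75.5 and 47.7 CPM in sarcomas 1, 2 and 4, and a merged peak of 10271 bp held 187 CPM in sarcoma 3. At Rosa26 (Gt(ROSA)26Sor), where the number of reporter alleles differs, the peak held 139 CPM in fascia and 119, 130, 160 and 64.8 CPM in sarcomas 1 to 4.

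**Figure D1:**
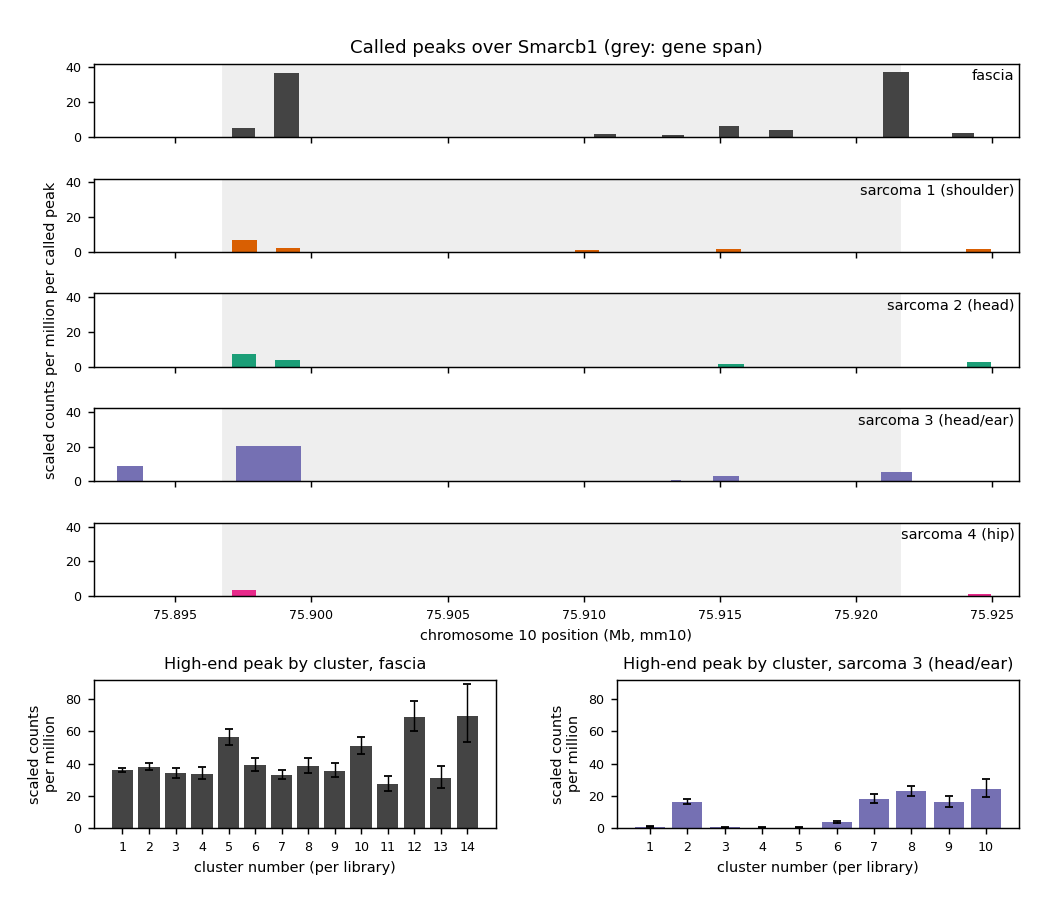
Called peaks over Smarcb1 in each library (upper panels, scaled CPM per peak against the mm10 position on chromosome 10, bar width equal to the peak's width, grey for the gene) and the level of the high-end peak in each cluster of fascia and of sarcoma 3 (lower panels, error bars for 95% exact Poisson intervals, which cover counting error only). The high-end peak held 37.5 CPM in fascia and 5.60 CPM in sarcoma 3, was not called in the other sarcomas, and in sarcoma 3 sat mainly in clusters 2 and 7 to 10.

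The comparison of sarcomas with fascia asked which gene promoters were more or less accessible in the tumours than in the progenitors of the same lineage. The gene end with the most counts stood in for the promoter, and it may not be the transcription start. Some members of the fixed gene lists lay on the same side of fascia in every sarcoma, although no gene passed edgeR's test. The stem and progenitor surface genes Ly6a (19.4 CPM in fascia, 2.33 ± 1.30 in sarcomas, SD, n = 4), Dpp4 (14.4 against 1.69 ± 0.893) and Cd34 (37.1 against 4.70 ± 3.35) lay below fascia in every sarcoma. So did the scavenger receptor Scara5 (19.5 against 7.87 ± 0.973), the matrix gene Mfap5 (46.1 against 5.90 ± 4.88) and the mesenchymal transcription factor Twist2 (38.2 against 8.50 ± 5.53). The cell cycle inhibitor genes Cdkn2a (13.8 against 37.8 ± 9.40) and Cdkn2b (17.6 against 38.3 ± 1.96) lay above fascia in every sarcoma. So did the Hox genes Hoxb2 (4.73 against 48.0 ± 21.1), Hoxb4 (7.68 against 28.1 ± 5.52) and Hoxb5 (5.02 against 21.6 ± 6.89). By edgeR's quasi-likelihood test 0 of 12944 genes passed an adjusted p of 0.05 in either direction. At an unadjusted p under 0.05, 400 were higher and 357 lower, and DESeq2 called 216 higher and 103 lower. Every sarcoma lay above fascia at 2647 genes (20.4%) and below it at 2966 (22.9%), where chance gives 20% each.

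**Figure D2:**
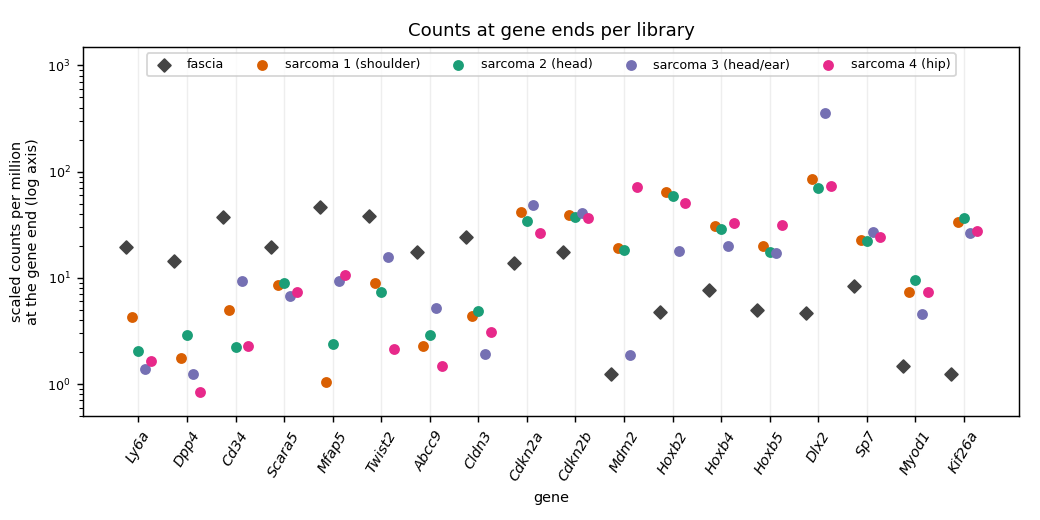
Scaled CPM (log axis) at the ends of 18 genes in each library, with fascia as diamonds and the 4 sarcomas as circles coloured by sample. Fascia lies above every sarcoma from Ly6a to Cldn3 (Cd34, 37.1 in fascia and 4.70 ± 3.35 in sarcomas, SD, n = 4) and below every sarcoma from Cdkn2a to Kif26a (1.25 against 30.9 ± 4.93).

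The largest differences that DESeq2 called with every sarcoma on the same side of fascia were 8 genes below it and 8 above. Below fascia lay Col6a6, a collagen VI chain (35.8 CPM in fascia, 2.31 ± 1.84 in sarcomas, SD, n = 4), Ifi205, an interferon-induced gene (48.7 against 3.25 ± 2.21), and Lrtm2 (29.8 against 2.16 ± 1.26). Also below it were Tubb4a, a tubulin (20.9 against 1.62 ± 0.756), the dynein Dnah3 (15.99 against 1.27 ± 0.261), ceruloplasmin, Cp (26.5 against 2.32 ± 1.103), Pamr1 (26.6 against 2.84 ± 1.25) and Adamtsl1 (32.3 against 3.49 ± 1.66). Above fascia lay Ifitm2, an interferon-induced membrane gene (4.23 against 137 ± 85.4), the homeobox gene Dlx2 (4.67 against 147 ± 141), the kinesin Kif26a (1.25 against 30.9 ± 4.93) and the protocadherin Pcdhb8 (0.645 against 12.8 ± 7.78). Also above it were the cholecystokinin receptor Cckbr (0.882 against 16.1 ± 13.7), Gchfr (3.52 against 60.4 ± 42.4), the prohormone convertase Pcsk1 (1.68 against 26.02 ± 22.0) and the histone H3c15 (0.836 against 12.8 ± 5.55). The 3 differences that shrank most when all peaks within 3000 bp were counted were those at Ifitm2, Kif26a and H3c15. Ifitm2 then held 92.1 CPM in fascia and 83.9, 113, 264 and 89.2 in sarcomas 1 to 4, Kif26a 21.4 against 53.4, 48.2, 32.6 and 40.2, and H3c15, whose window overlaps that of another gene, 14.9 against 29.1, 23.8, 16.5 and 18.1. Over gene bodies their log2 fold changes were 0.83, 0.76 and 0.67, with edgeR adjusted p of 0.669, 0.443 and 0.567. At its gene end Kif26a had a log2 fold change of 4.63 in edgeR's test with an adjusted p of 0.611. It was the only gene that edgeR called when gene ends with a peak over 2500 bp in any library were left out. In that edgeR test Kif26a had a log2 fold change of 4.66 and an adjusted p of 0.0291. Simulated data gave this fit 11 false calls, but beside many recovered genes, so that count may not carry over to a lone call. Dpp4 was among the 3 genes that edgeR called lower over gene bodies, with a log2 fold change of -4.61 and an adjusted p of 0.0490. Without sarcoma 3, 1495 genes had an unadjusted p under 0.05 in place of 757. The count was 521 without sarcoma 1 and 478 without sarcoma 2, and edgeR called 0 genes in each case.

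Among the 25 gene lists, camera placed mesenchymal progenitor and fibroblast genes lower and 4 lists higher in the sarcomas relative to the other genes. The fibroblast list fell (24 genes, median log2 fold change -0.11, camera adjusted p = 0.0129, adjusted p = 0.653 with an estimated correlation), with 8 members below fascia in every sarcoma and 2 above. Its median was above 0 without sarcoma 1 (0.0015), 2 (0.07) or 4 (0.10) and -0.61 without sarcoma 3. Of its members 0 passed edgeR over all genes and 2, Ly6a and Dpp4, passed adjusted over the list alone. The largest member by size was Meox1, at 2.71 CPM in fascia and 27.2 ± 23.2 in sarcomas (SD, n = 4), which sarcoma 4 held at 2.62. Head mesenchyme transcription factors rose as a list (19 genes, median 0.50, camera adjusted p = 0.0248, adjusted p = 0.653 with an estimated correlation), led by the neighbouring genes Dlx1 (0.981 against 106 ± 168) and Dlx2, which shared a peak of 21374 bp in sarcoma 3. Cell cycle inhibitors and p53 targets rose as a list (13 genes, median 0.39, camera adjusted p = 0.0395, adjusted p = 0.653 with an estimated correlation), with 7 members above fascia in every sarcoma and 1 below. Its largest member was Mdm2, which encodes the ligase that degrades p53, at 1.24 CPM in fascia and 27.8 ± 30.5 in sarcomas, and Cdkn2b passed adjusted over the list alone. Skeletal muscle genes rose as a list of only 4 genes (median 1.45, camera adjusted p = 0.0395, adjusted p = 0.653 with an estimated correlation), led by Myod1 (1.49 against 7.22 ± 2.02) and Tnnt3 (3.46 against 11.1 ± 5.83). Within 3000 bp Tnnt3 held 10.07 CPM in fascia and 4.83 to 17.7 in the sarcomas. The Hox genes rose as a list (25 genes, median 0.71, camera adjusted p = 0.0397, adjusted p = 0.653 with an estimated correlation), with 7 members above fascia in every sarcoma and 2 below. The 7 include Hoxb7 and Hoxb8, whose levels were identical in every library, so they are not separate observations. Without sarcoma 4 the adjusted p was 0.138 for the fibroblast list and 0.413 for the Hox genes, and without sarcoma 1 it was 0.0711 for the Hox genes and 0.0655 for both the p53 and the muscle lists. With gene ends under peaks over 2500 bp left out, the head mesenchyme (0.349), muscle (0.1495) and Hox lists (0.679, now downward) did not pass camera, and the fibroblast and p53 lists did. These lost their call too, with adjusted p = 0.213 and adjusted p = 0.335 with an estimated correlation, and passed fry (0.0418 and 0.0171). With clusters of raised markers left out, the 4 lists that rose had an adjusted p of 0.0609 each.

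The other 20 lists did not pass camera, and their largest members are given as values. Bone, cartilage and tendon genes (adjusted p = 0.128) included the osteoblast factor Sp7 (8.40 CPM in fascia, 24.0 ± 2.12 in sarcomas, SD, n = 4), which passed edgeR adjusted over the list alone, and the tendon factor Mkx (7.95 against 21.4 ± 15.6). The epithelial list (0.489) held the claudin Cldn3 (24.3 against 3.56 ± 1.33), which also passed adjusted over the list alone, and Spint1 (2.55 against 5.96 ± 4.49). Cyclin D, MYC and growth regulators (0.139) held Cdk6 (2.45 against 27.5 ± 37.9) and Ccnd1 (9.01 against 51.0 ± 48.2). Proliferation genes (0.250) held Rrm2 (28.7 against 52.7 ± 10.2) and Plk1 (18.3 against 29.3 ± 7.47). SWI/SNF subunits (0.972) and Polycomb subunits (0.993) had median log2 fold changes of 0.02 and 0.07. Their largest members were Arid1b at 24.7 against 43.3 ± 27.5, Smarcd3 at 5.16 against 3.18 ± 1.85, Ring1 at 29.8 against 65.3 ± 65.5 and Phf19 at 18.4 against 9.62 ± 4.10. The pericyte and smooth muscle list (0.104) held Tbx2 (8.65 against 58.2 ± 47.7) and Abcc9 (17.6 against 2.94 ± 1.58), and had a camera adjusted p = 0.00432 without sarcoma 3 (adjusted p = 0.704 with an estimated correlation) and a camera adjusted p = 0.0121 with peaks up to 2500 bp (adjusted p = 0.804 with an estimated correlation). TGF-beta and matrix remodelling genes (0.250, and without sarcoma 3 camera adjusted p = 0.0190 but adjusted p = 0.704 with an estimated correlation) held Ccn1 (12.9 against 77.7 ± 86.7) and Mmp2 (30.8 against 8.27 ± 13.5). Interferon and antigen presentation genes (0.107, and without sarcoma 2 camera adjusted p = 0.0368 but adjusted p = 0.836 with an estimated correlation) held H2-K1 (53.6 against 31.1 ± 13.1) and Psmb8 (41.3 against 25.1 ± 5.92). Limb and trunk factors (0.972) held Tbx15 (12.4 against 104 ± 190) and Meis2 (18.1 against 87.1 ± 100.1). Neural genes (0.295) held Stmn2 (1.44 against 14.4 ± 9.96) and Sox2 (4.12 against 19.4 ± 13.4), and Hedgehog and WNT genes (0.282) held Gli1 (16.9 against 59.9 ± 38.9) and Dkk2 (17.3 against 43.3 ± 27.7). AP-1 genes (0.972) held Batf (1.09 against 4.05 ± 1.54) and Maff (84.3 against 35.8 ± 16.3). EMT factors (0.972) held Twist1 (47.1 against 110 ± 102) and Zeb2 (25.5 against 46.4 ± 68.1). Housekeeping genes (0.972) held Actb (38.4 against 87.7 ± 70.6). For other cell types, the immune list (0.179) held Cd68 (5.48 against 28.1 ± 33.5) and Cd79a (19.4 against 50.4 ± 62.2). The endothelial list (0.310) held Sox18 (2.49 against 6.98 ± 3.00) and Sox17 (1.52 against 4.08 ± 2.68), and the adipocyte list (0.993) held Cebpa (51.5 against 88.6 ± 15.8) and Pparg (9.89 against 6.20 ± 2.51). The Schwann cell list (0.489) held Foxd3 (1.09 against 7.64 ± 5.00) and Ncam1 (9.39 against 17.6 ± 6.30), and the melanocyte list (0.310) Ednrb (2.28 against 5.40 ± 1.98) and Kit (4.78 against 6.79 ± 1.98). The camera direction was down and the median above 0 for the epithelial (0.20, mean -0.10), AP-1 (0.16), housekeeping (0.07), Polycomb and SWI/SNF lists, and up with a median of -0.18 for the adipocyte list. Without sarcoma 4 the bone list had a camera adjusted p = 0.0383 (adjusted p = 0.749 with an estimated correlation).

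The sets of called peaks at gene ends also differed between fascia and the sarcomas. Strand was not known, so the end used for a gene may not be its promoter. A called peak was present at the end of 763 genes in fascia and in no sarcoma, and at 102 genes in every sarcoma and not in fascia. The strongest fascia peaks that no sarcoma had lay at Impg2 (36.9 CPM), Cd96 (33.7), the keratin gene Krt36 (31.9), Hhipl2 (30.4), Galnt16 (27.3), Olfr267 (24.5), Ces2b (24.2) and Nmnat2 (23.3). A sarcoma peak lay within 3000 bp of Cd96, Olfr267, Ces2b and Nmnat2. Of the fixed lists, the limb factor Tbx4 (9.39 CPM), the epithelial genes Trp63 (3.01) and Pkp3 (1.16), the neural crest factor Sox10 (1.28) and the melanocyte genes Dct (1.74) and Tyrp1 (0.752) had a peak in fascia alone. So had Tgfb2 (2.97), Lef1 (0.897), Dcx (0.718), Myh1 (2.72), Lep (1.24), Fcer1g (1.34), Bglap (5.25) and Tnmd (0.741). The strongest sarcoma peaks that fascia lacked lay at Kat6b (106 ± 63.2 CPM, SD, n = 4), Naif1 (90.5 ± 12.6), Fads6 (74.1 ± 14.9), Fbxl18 (67.5 ± 87.6), Dvl3 (64.5 ± 13.1), Sh2b2 (60.4 ± 23.7), Zfp771 (55.4 ± 5.23) and Furin (54.7 ± 17.6). Fascia had, however, a peak between 1005 and 1191 bp away at the first 7 and 2326 bp away at Furin. At Fbxl18 the level in sarcoma 3 was 193 CPM, equal to its level at Actb, where the peak covered 16177 bp. With no fascia peak within 3000 bp, a rule set after these values were seen, 42 genes remained. They included the homeobox gene Tlx2 (29.5 ± 31.1), Zfp532 (25.96 ± 29.0), the potassium channel gene Kcnf1 (12.9 ± 8.38), Eva1a (9.14 ± 3.69), Spint2 (7.60 ± 9.03), the ghrelin receptor Ghsr (7.03 ± 2.97) and Adcyap1 (5.77 ± 8.66). List members with a peak in every sarcoma alone included Itgam (4.42 ± 1.73) and, with a fascia peak within 3000 bp, Cdkn1a (49.8 ± 68.4), Esrp1 (5.53 ± 1.51), Nkx2-2 (4.20 ± 1.65) and Mmp9 (2.88 ± 0.124). Fascia had 197002 peaks against 88429 to 97759 in the sarcomas, and with the 88429 densest peaks of each library 649 genes had a peak in every sarcoma alone and 184 in fascia alone. Among all called peaks, 177 genes had a peak in every sarcoma alone without sarcoma 3, in place of 102.

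A lone sarcoma moved many of these means by over 1.5 times. Without sarcoma 3 the mean fell below fascia at Tbx15 (9.16 CPM), Zeb2 (12.4) and Cd79a (19.4), and lay close to it at Ring1 (32.6). It also fell to 22.4 at Dlx1, 76.4 at Dlx2, 16.9 at Meox1, 13.6 at Mkx, 8.59 at Cdk6, 27.5 at Ccnd1, 36.6 at Tbx2, 34.5 at Ccn1, 1.52 at Mmp2, 37.0 at Meis2, 12.7 at Sox2, 59.6 at Twist1, 52.5 at Actb and 11.4 at Cd68. Among genes without a fascia peak it fell to 15.6 at Cdkn1a, 25.7 at Fbxl18, 14.2 at Tlx2, 11.5 at Zfp532 and 1.45 at Adcyap1. Without sarcoma 4 it was 13.1 at Mdm2, which sarcoma 3 held at 1.89, 3.89 at Spint1 and 3.09 at Spint2. Without sarcoma 2 it was 10.6 at Cckbr and 15.7 at Pcsk1, and without sarcoma 1 it was 1.41 at Col6a6.

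Among regions called in all 5 libraries, those away from gene ends had a higher median log2 fold change than those at gene ends. Regions that any sarcoma lacked were left out, and fascia had the most peaks. This filter can itself favour regions that are high in the sarcomas, which was not tested. Of 42625 merged regions with a peak in all 5 libraries, the 11735 at a gene end had a median log2 fold change of -0.08 and the other 30890 one of 0.27, sarcoma over fascia. edgeR's quasi-likelihood test called 0 regions in either direction, 5286 had an unadjusted p under 0.05, and 4607 of these lay away from gene ends. DESeq2 called 1111 higher and 1641 lower, and edgeR called 26 higher and 481 lower with an offset for peak width and 10 higher and 583 lower with clusters of raised markers left out. Without sarcoma 3 the count at an unadjusted p under 0.05 was 8737, and without sarcoma 2 it was 3490.

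The order of similarity among the libraries changed with the measure. The Jaccard index of base pairs in peaks was 0.581 between sarcomas 1 and 2, 0.452 and 0.457 between these and sarcoma 4, and 0.290 to 0.354 between sarcoma 3 and the others, with a mean of 0.412 over the 6 pairs. It was 0.304, 0.309, 0.281 and 0.253 between fascia and sarcomas 1 to 4. Of the sarcoma peaks, 22.9%, 20.6%, 13.9% and 27.8% in sarcomas 1 to 4 had no fascia peak under them. As shares of the smaller set's peaks the order turned, since fascia peaks overlapped 78.7% of a sarcoma's peaks on average and sarcoma peaks overlapped 67.9% between sarcomas. With the 88429 densest peaks of each library these shares were 59.1% and 71.2%. With 1 fascia library the smallest p that a permutation can give is 0.2, so no test was made of this and the next comparison.

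Counts in the sarcomas were concentrated at gene ends. Peaks within 1000 bp of a gene end held 31.1% of the counts in fascia and 46.3% ± 4.20 (SD, n = 4) in the sarcomas, with 43.8%, 42.5%, 51.9% and 47.2% in sarcomas 1 to 4. Such peaks made up 8.43% (interval 8.31 to 8.56) of fascia peaks and 15.4% ± 1.06 of sarcoma peaks. With the 88429 densest peaks of each library the shares of peaks were 15.96% and 16.2% ± 1.05, and the shares of counts 34.2% and 46.5% ± 4.10.

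Chromosome 4 held a smaller share of counts in the hip tumour than in any other library. Over 2658 regions called in all 5 libraries its share of counts was 6.21% in fascia and 6.34%, 6.36%, 6.40% and 4.81% in sarcomas 1 to 4, a log2 ratio to fascia of -0.37 in sarcoma 4 and 0.03 to 0.04 in the others. Chromosome 17 in sarcoma 4 had a log2 ratio of 0.16, but 0.03 over gene ends and 0.33 over other regions. Chromosome X lay between 0.10 and 0.21 in the 4 sarcomas, with -0.03 to 0.10 over gene ends and 0.17 to 0.35 over other regions. All other autosomes lay between -0.11 and 0.10. No peak was called at the ends of the chromosome Y genes Ddx3y, Uty, Kdm5d, Eif2s3y and Sry in any library. All 5 libraries had peaks over Xist, the RNA gene of the inactive X chromosome. Before scaling these held 26.1 CPM in fascia and 54.2 to 62.1 CPM in the sarcomas. Division by the library factors (0.724 for fascia, 1.02 to 1.16 for the sarcomas) would narrow this difference.

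**Figure D3:**
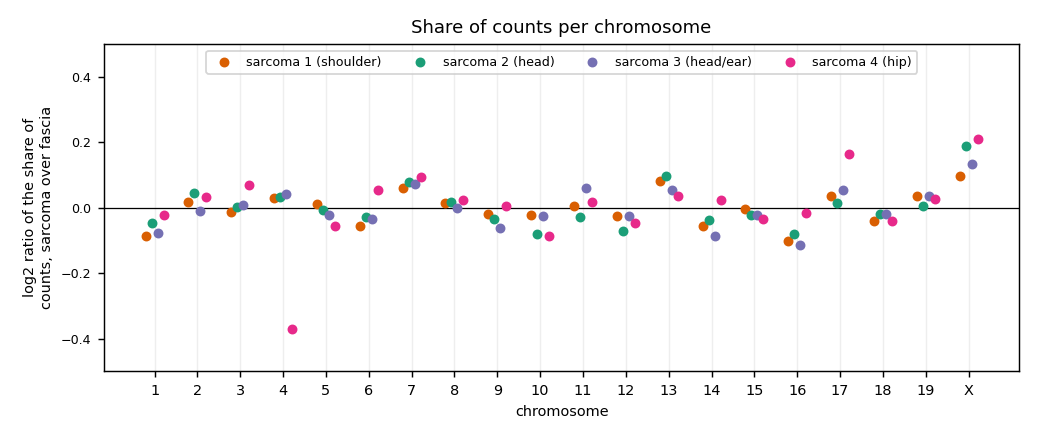
Log2 ratio of each chromosome's share of counts, sarcoma over fascia, over regions with a peak in all 5 libraries, with a point per sarcoma. Chromosome 4 in sarcoma 4 lies at -0.37, and the other 3 sarcomas lie between 0.03 and 0.04 there.

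The comparison of head with body sarcomas asked whether the tumours differed by site. Sarcomas 2 and 3 came from the head and sarcomas 1 and 4 from the shoulder and hip. The Hox genes, which mark position along the body axis, were lower as a list in the head sarcomas, and fibroblast genes were higher. The Hox list fell (25 genes, median log2 fold change -0.93, camera adjusted p = 3.15e-06, adjusted p = 0.577 with an estimated correlation) and the fibroblast list rose (24 genes, median 0.81, camera adjusted p = 3.15e-06, adjusted p = 0.577 with an estimated correlation). The Hox list counts Hoxb7 and Hoxb8 as separate members, although their levels were identical in every library. Counts over the Hoxc cluster were 131 and 217 CPM in sarcomas 2 and 3, against 398 and 774 CPM in sarcomas 1 and 4. Hoxb held 407 and 295 against 504 and 721 CPM, and Hoxa 373 and 157 against 301 and 550 CPM. Hoxd held 538 CPM in sarcoma 2 and 119 to 258 CPM in the other sarcomas. Summed over Hox genes numbered 9 to 13, gene ends held 158, 174, 159 and 417 CPM in sarcomas 1 to 4. There the hip sarcoma alone was high. Genes numbered 6 to 8 held 309, 155, 209 and 214 CPM, and those numbered 1 to 5 held 278, 380, 210 and 329 CPM. In fascia the Hoxa, Hoxb, Hoxc and Hoxd clusters held 359, 118, 383 and 135 CPM, so that Hoxb lay above fascia in every sarcoma, over 26.9 kb of peaks in fascia and 30.7 to 57.2 kb in the sarcomas. Hoxc9 and Hoxc13 had no peak in sarcoma 2 and held 7.83 and 4.24 CPM in sarcoma 3. In the body sarcomas they held 5.65 and 3.85 CPM (sarcoma 1) and 52.4 and 50.1 CPM (sarcoma 4). Hoxa5 had no peak in sarcoma 4 and held 35.3, 52.1 and 9.75 CPM in sarcomas 1 to 3.

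**Figure D4:**
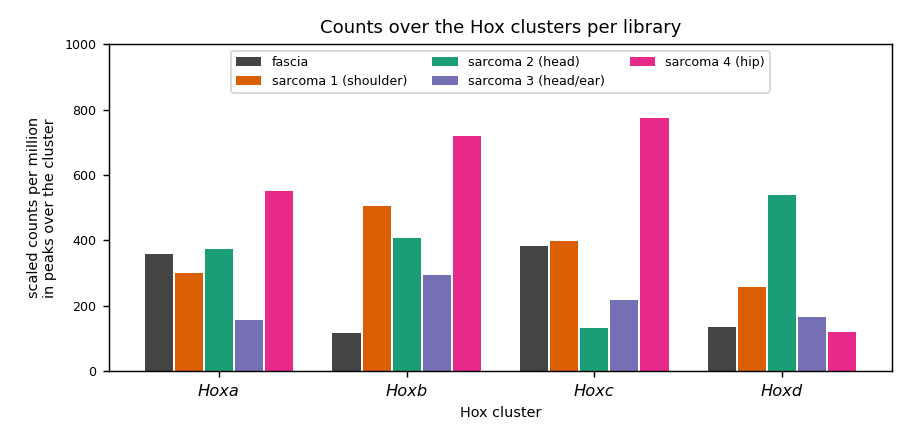
Scaled CPM in peaks over each Hox cluster, with a bar per library. Hoxb is lowest in fascia (118), Hoxc is highest in the hip sarcoma (774), and Hoxd is highest in the head sarcoma (538).

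Camera placed 7 other lists higher in the head sarcomas. With Benjamini-Hochberg adjustment they were TGF-beta and matrix remodelling (camera adjusted p = 0.000155), pericyte and smooth muscle (0.000336), AP-1 (0.000430), EMT factors (0.000430), Hedgehog and WNT (0.00174), head mesenchyme factors (0.0279) and Polycomb subunits (0.0409). Each lost its call, with adjusted p = 0.577 with an estimated correlation for all but the Polycomb subunits, where adjusted p = 0.639 with an estimated correlation. Sarcoma 3 led at most of their largest members, such as the collagen Col6a1 of the fibroblast list (10.3 and 158 CPM in sarcomas 2 and 3, 11.1 and 6.28 in sarcomas 1 and 4), the TGF-beta inhibitor Smad7 (73.6 and 247 against 31.4 and 46.7) and the smooth muscle actin Acta2 (3.50 and 47.0 against 5.18 and 0.788). The AP-1 gene Fosb (36.0 and 334 against 54.0 and 44.6) and the EMT factor Zeb2 (18.1 and 148 against 14.8 and 4.41) had the same pattern, and the WNT inhibitor Dkk3 (4.46 and 15.3 against 1.71 and 2.56) was higher in both head sarcomas. The 16 lists that did not pass had camera adjusted p from 0.0633 to 0.690. Sarcoma 3 held 29.3% of its barcodes in clusters with at least 3 raised markers of a cell type, fibroblasts included. The share was 4.99% in sarcoma 2, 4.74% in sarcoma 1 and 0.835% in sarcoma 4, where the leading type was fibroblasts. With gene ends under peaks over 2500 bp left out, the Hox genes, pericyte, and Hedgehog and WNT lists kept their calls and directions, at adjusted p of 3.09e-06, 0.00496 and 0.0418, and interferon and antigen presentation genes were also higher in the head sarcomas (0.0176), and for all 4 adjusted p = 0.682 with an estimated correlation. The fibroblast list, with 6 genes left, did not pass (camera adjusted p = 0.458).

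For single genes, edgeR's quasi-likelihood test called 0 of 13046 between head and body sarcomas, with 268 at an unadjusted p under 0.05. DESeq2 called 22 higher and 1 lower in the head sarcomas, and edgeR with an offset for peak width called 3 higher and 4 lower. The highest by DESeq2 were Mical1 (17.5 and 58.2 CPM in sarcomas 2 and 3, 1.86 and 2.24 in sarcomas 1 and 4), the integrin Itgb6 (8.13 and 135 against 4.08 and 4.22), Chst13 (16.6 and 17.4 against 1.20 and 0.855), and the homeobox gene Irx5 (71.2 and 232 against 11.2 and 13.2). They also included Dnm3 (25.5 and 121 against 6.93 and 5.78), Trp53bp1 (18.3 and 20.2 against 2.43 and 1.04), the ligand Wnt11 (24.5 and 93.5 against 4.62 and 6.36) and Armh4 (14.5 and 9.78 against 1.59 and 0.776). Pfdn1 was lower, at 9.38 and 4.27 against 40.8 and 38.6 CPM. In sarcoma 3 the peaks counted at these genes covered 2544 to 19561 bp, except at Armh4 (903 bp) and Pfdn1 (1086 bp). With all peaks within 3000 bp counted, Mical1 held 57.9 and 58.2 against 30.4 and 54.4 CPM, Itgb6 8.54 and 135 against 14.7 and 4.22, Dnm3 51.96 and 121 against 40.7 and 21.4, Irx5 157 and 232 against 84.3 and 70.2, and Wnt11 82.2 and 93.5 against 47.2 and 44.2. With sarcoma 1 left out, edgeR called 52 genes higher and 20 lower, a fit with a lone body sarcoma that was assumed to vary like the head sarcomas. The counts at an unadjusted p under 0.05 were then 990, and 1527 without sarcoma 2 and 161 without sarcoma 3.

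Each sarcoma also had genes that set it apart from the other 3, described without a test. In sarcoma 1 the death receptor gene Tnfrsf26 (29.2 CPM, log2 difference 4.20 from the mean log2 level of the others), Arap3 (27.9, 3.74) and Tank (26.4, 3.86) were high, although sarcoma 2 held Tank at 24.3 CPM, and the zinc finger gene Tshz2 (2.18, -4.07) was low. In sarcoma 2 Pcdha9 (22.5, 4.16) and the urokinase gene Plau (36.1, 4.05) were high and Mab21l2 (1.32, -4.20) and Eml1 (1.56, -4.12) were low. Sarcoma 3 led at Tbx15 (390.1, 5.44), Dlg4 (288, 5.40), Popdc2 (65.0, 5.28) and Vamp2 (601, 5.09), all under peaks of 5601 to 40898 bp, and per base pair of peak the log2 differences were 1.28, 1.98, 3.67 and 0.93. In sarcoma 4 Gcnt2 (78.0, 4.79) was high, and the matrix genes Emilin1 (2.78, -5.21) and Lum (0.855, -4.82) and the retinoic acid binding gene Crabp1 (0.909, -4.76) were low, although with all peaks within 3000 bp counted Emilin1 held 45.1 CPM there.

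Clusters named after other types than fibroblasts made up small parts of 3 libraries. Pericyte and smooth muscle-like clusters held 386 of 9977 barcodes in fascia (3.87%, exact binomial interval 3.50 to 4.27) and 153 in sarcoma 2 (1.45%, 1.23 to 1.69), and an endothelial-like cluster, led by Lyve1 and Tie1, held 164 barcodes in sarcoma 3 (1.40%, 1.20 to 1.63). In sarcomas 1 and 4 no cluster passed the rules for a name. Other clusters had at least 3 raised markers of a type and stayed unnamed, and the shares above leave them out. The largest was cluster 2 of sarcoma 3 (2491 barcodes, 21.3%), with 3 of 7 adipocyte markers raised. Of 10 pericyte markers, 8 were raised in cluster 5 of fascia (378 barcodes, 3.79%), 7 in cluster 8 of sarcoma 3 (377, 3.22%), and 6 and 4 in clusters 7 and 6 of sarcoma 1 (135 and 239, 1.71% and 3.03%). Of 10 tendon, cartilage and bone markers, 3 and 4 were raised in clusters 9 and 13 of fascia (2.68% and 1.05%) and 3 in cluster 7 of sarcoma 3 (3.43%). Cluster 14 of fascia (0.441%) had 6 of 12 endothelial markers raised. The 10 highest genes of unnamed clusters included Chad and the tendon factor Scx in cluster 7, Higd1b and desmin, Des, in cluster 8 and Ifi205 and Efemp1 in cluster 2 of sarcoma 3, and Dpt and Thbs2 in cluster 9 of sarcoma 4. All libraries were sorted on tdTomato, which sets which types can appear. The names were rebuilt from fixed markers and are not the authors' own.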

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

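The tests of the Smarcb1 pattern were written after its values had been seen, and those of chromosome 4 before their own values were computed. Of 144 values per sarcoma that were compared, 37 stood out because 1 sarcoma lay far from the other 3 by Dixon's test, where chance makes about 1 in 20 groups do so. That rate does not carry over to this set, since it includes genes picked for a lone sarcoma and genes that share a peak, such as Dlx1 and Dlx2. Of the 37, 29 were in sarcoma 3, the library with another software version, and 47.3% of its counts lay in peaks over 2500 bp, a width that no other library reached.

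Smarcb1 had a high-end peak of 5.60 CPM in sarcoma 3 and none called in the other sarcomas. Free fragments in the droplets would spread the peak evenly over clusters. Its level differed 178-fold between the highest and the lowest cluster of sarcoma 3, which excludes an even spread as the main source. The other software version stays open as a reason why the peak was called in no other sarcoma. The spread within sarcoma 3 cannot test this, since counts outside called peaks were not used in the other sarcomas. Cells that kept the gene, such as host cells or cells without recombination, stay open. The sort for tdTomato selects against cells without a recombined reporter, and its purity was not measured here. The lowest of the clusters with raised markers of other types (2, 7, 8 and 10) was 1.00 times the highest of all other clusters, which was cluster 9, so markers and peak did not part the clusters alike. The counts do not separate host cells from tumour cells that kept an allele.

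Chromosome 4 in sarcoma 4 had a log2 ratio to fascia of -0.37, where the other sarcomas had 0.03, 0.03 and 0.04. A few strongly changed regions would leave the typical region in place, but the median over chromosome 4 regions lay at -0.335 (log2) relative to other autosomes. The share of chromosome 4 in cluster 9, whose 121 barcodes had raised fibroblast genes such as Dpt, was 16.1% above that of the other clusters. At 5.69% of the counts in its library's autosomal peaks (interval 5.64 to 5.74), it still lay below fascia (6.23%) and sarcomas 1 to 3 (6.44% to 6.58%). Lost copies in the tumour cells could account for the low share, but cluster 9 did not reach the level of the other libraries. Whether its cell type alone shifts the share was not tested. DNA copy number was not measured here.

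At gene ends, 34 of 108 named genes stood out because 1 sarcoma lay far from the others. They include 9 of the 16 genes picked because a lone sarcoma differed, and 25 of the other 92, of which 22 were in sarcoma 3. In all, 26 of the 27 in sarcoma 3 lay under a peak over 2500 bp. In sarcoma 3 the high values, in CPM, were Actb 193, Adcyap1 18.8, Ccn1 207, Cd68 78.1, Cd79a 143, Cdk6 84.2, Cdkn1a 152, Dlg4 288, Dlx1 358, Dlx2 358, Foxd3 15.1, Ifitm2 264, Itgb6 135 and Mab21l2 122. The others there were Meis2 237, Mkx 44.6, Mmp2 28.5, Nkx2-2 6.68, Popdc2 65.0, Ring1 163, Sox2 39.4, Tbx15 390.1, Twist1 262, Vamp2 601, Zeb2 148, Zfp532 69.3 and Zfp771 63.3. Sarcoma 1 stood apart with high values at Tnfrsf26 (29.2) and Arap3 (27.9) and a low value at Kat6b (12.1). Sarcoma 2 was high at Pcdha9 (22.5), and sarcoma 4 at Gcnt2 (78.0), Kcnf1 (25.4) and Spint2 (21.1).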

How the results depend on the processing

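Alternatives with peaks up to 2500 bp, raised clusters left out, both gene ends, no peak within 3000 bp and levels per base pair were chosen after the data had been seen, and for each change below the cause was not tested. For promoters of sarcomas against fascia, edgeR's 0 calls became 198 with a width offset (46 higher, 152 lower), 1 with peaks up to 2500 bp, 228 with both, 3 over gene bodies and 6 with uncalled peaks as 0, and DESeq2 called 319. Regions gave 507 with a width offset (26 higher, 481 lower), 593 with raised clusters left out (10 higher, 583 lower) and 2752 by DESeq2. Head against body gave 7 with a width offset (3 higher, 4 lower), 23 by DESeq2 and 0 to 72 with each sarcoma left out. The median log2 fold change of all genes was 0.02, but -0.18 with the width offset and -0.14 with peaks up to 2500 bp and the offset. Between head and body it moved from -0.01 to -0.47 with the offset and -0.11 with total counts, and for regions from 0.11 to 0.24 with total counts. Genes with a peak in every sarcoma alone numbered 649 with the densest peaks, 354 at 2 CPM, 42 with no peak within 3000 bp and 116 to 177 with each sarcoma left out, and those in fascia alone 184, 339 and, where the peak covers the gene end, 502. Against fascia 5 lists were called, and 0 with an estimated correlation, 0 by fry, 2 to 7 with each sarcoma left out, 3 with peaks up to 2500 bp (2 of the 5) and 1 with raised clusters left out. The Hox list turned downward with peaks up to 2500 bp (camera adjusted p = 0.679). Between head and body 9 lists were called, and 0 with an estimated correlation, 0 by fry and 4 with peaks up to 2500 bp (3 of the 9). The ratio of a sarcoma's mean similarity to the other sarcomas to that with fascia, averaged over the 4 sarcomas, was 1.44 and turned to 0.867 as a share of the smaller set and 0.788 with reciprocal overlap. The difference in gene-end share fell from 6.96 to 0.232 percentage points with the densest peaks. Chromosome 4 in sarcoma 4 lay at -0.40 over gene ends and -0.33 elsewhere, and the pericyte-like share of fascia at 4.33% without barcodes over 3 times the median. Of the named genes' alternatives against fascia 1076 stayed uncalled and 56 became calls, and between head and body 99 and 11. DESeq2 was among these alternatives, and its calls had picked part of the genes against fascia and all of those between head and body. Its calls at those genes were thus fixed in advance. Sarcoma 2, with the fewest counts, sets the depth limit. The motif alternatives (central 400 bp, densest peaks) were not run. No paired analysis was made, since the labels do not say which libraries, if any, came from the same animal.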

Other observations

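Of the tests of chromosome Y below, the one on depth was written after the values had been seen. The titles of all samples end in XX, and the labels do not say whether this marks the sex. Over 7 regions called in all 5 libraries at the far end of chromosome Y, between 90737339 and 90813310, the sarcomas had log2 ratios to fascia of 2.00, 2.27, 1.30 and 1.14. Over all peaks on chromosome Y the unscaled levels were 47.3 CPM in fascia and 292, 336, 166 and 169 CPM in sarcomas 1 to 4. Such counts at chromosome Y positions do not show how much of the chromosome a library held. The only annotated gene end with a peak there was Gm52481, a predicted gene, at 7.35 CPM in fascia and 32.8, 48.7, 58.1 and 17.0 CPM in the sarcomas.

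No library had a peak at the 5 chromosome Y genes examined and all had peaks over Xist. These counts thus do not show which barcodes, if any, carry the chromosome. The excess of barcodes without a chromosome Y count was 3.06 percentage points in fascia and 2.41, 1.72, 5.64 and 3.09 in sarcomas 1 to 4. Fascia thus did not stand out, and these counts cannot test a mixture of cells with and without the chromosome. The deeper fascia library with more called peaks could lower the share, but over regions called in all 5 libraries the lowest sarcoma still lay at 1.14 (log2) above fascia. No biological explanation other than the mixture was examined.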
